A study of Mus musculus with 2 samples.

How the data were processed

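H3K4me3 ChIP-seq had been done on the intestine of newborn mice in 2 biological replicates of 1 group, each a pool of animals of mixed sex. The deposited files were 4 peak lists in narrowPeak format on the mm10 genome. Per the file headers and the accompanying description, the authors called peaks on each replicate and on both together against control alignments, and derived the replicated list from those calls. The deposited signal column is the enrichment of a peak as the authors' peak caller gave it. Its scale, the peak caller and the read depth of each sample were not given in the sources used here, so the signal was used only to rank peaks and to describe or filter them within a list, and no value was compared between the replicate lists as a level. Replicated peaks had the same signal as the pooled peaks they came from, so these lists share a scale. The authors also gave a −log10 p and a −log10 q for each peak, and the q served as a stricter filter. The deposited summit column is a distance in bp from the peak start. No reads were processed here, no control samples were among the samples, and precision from depth could not be given. Exact binomial intervals (95%) cover counting error only.

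Before use, peak coordinates were checked against the chromosome lengths of GRCm38.p6, which is mm10, and no peak reached beyond a chromosome end. Peaks on unplaced or unlocalized scaffolds were left out of all comparisons (17 in replicate 1, 35 in replicate 2, 42 in the pooled list and 12 in the replicated list), since few annotated starts lie there. Genes and transcript starts came from GENCODE release M21. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

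A gene counted as marked when a replicated peak overlapped the window of 1 kb on either side of any of its annotated starts. Replicate peaks counted as shared with at least 1 bp of overlap, and chance was measured with 100 random shifts of each list along its chromosomes. A domain was a run of replicated peaks joined over gaps of up to 1 kb, and a gene's domain was the widest that touched the window around its starts. Replicate domains were built the same way from each replicate's list, and their mean and SD (n = 2) are given. Promoters were put in the high-CpG class when any 500 bp window from 500 bp before to 2 kb after the start, moved in steps of 10 bp, had an observed-to-expected CpG ratio above 0.75 and a GC content above 55%. They were put in the low class when no window had a ratio above 0.48, and in the intermediate class otherwise. Repeated sequence was measured as the share of 32-base words within 1 kb of a gene's start that occurred elsewhere in the genome, with 500 marked high-CpG genes drawn at random for comparison.

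The design gave no comparison between groups of samples. Each of 37 gene lists was compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05 on the adjusted p. The width of domains was tested for the 29 lists with at least 5 marked members by a two-sided permutation test of the median against 10000 random lists of the same number of marked genes, adjusted over the 29 lists. The smallest p that these random lists can give is 0.0002. Membership in the widest 5% of domains was tested by Fisher's exact test over the same 29 lists. Both tests were tested on simulated data with 21938 genes and lists of 25. All 10 lists planted above and all 10 planted below were recovered, 8 of 10 lists planted with 1.6-fold wider domains were, and none of 40 null lists was called by either test. The planted differences in marked share were large, and marks and widths were drawn independently across genes, without CpG classes or shared domains. The simulation therefore does not show how the tests behave for smaller lists, smaller differences or genes that share domains.

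The lists covered the cell types of the intestine (enterocytes, epithelial regulators, crypt progenitors, goblet, Paneth, enteroendocrine and tuft cells, smooth muscle, fibroblasts, enteric neurons and glia, interstitial cells of Cajal, blood and lymphatic endothelium, leukocytes, erythroid cells and mesothelium). They also covered other organs (exocrine pancreas, liver, stomach, cardiac and skeletal muscle, forebrain, kidney, lung, epidermis, testis and oocyte), pathways and complexes (proliferation, Wnt, Notch, Hedgehog and BMP, ribosomal proteins, respiratory chain and proteasome), and the olfactory, vomeronasal and Hox families. The Paneth gene Pla2g2a and the erythroid gene Ahsp had no match among annotated protein-coding genes. Lists share some genes, for example Ptch1, Gli1 and Bmp4 between the mesenchymal list and the Hedgehog and BMP list.

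The samples, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 genes with the widest promoter domain and the 10 with the best worse rank of enrichment over both replicates. From each list it named the 2 marked members with the widest domain and the first 2 unmarked members in list order, or complete sets for lists of at most 30 members. It also named all Hox genes, the 5 strongest replicated peaks farther than 10 kb from a start and the 5 strongest unshared peaks of each replicate. Alternatives tried were windows of 0.5 and 2.5 kb, gene 5′ ends only, a −log10 q of at least 5, peaks of above-median enrichment, the pooled list, each replicate alone, a background without receptor families, high-CpG promoters only, and random lists matched on promoter CpG ratio. Stricter definitions of overlap, other ways of joining peaks and other distances from a start were also tried. Leaving out a replicate meant using the other replicate's own list, which had not passed the step that gave the replicated list.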

Results

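Trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark found mainly at active and poised promoters, was profiled by ChIP-seq in the intestine of newborn mice (P0) of mixed sex. The series held 1 group of 2 biological replicates, each a pool of animals. Replicate 1 was a pool of 15 mice, and the number of mice in replicate 2 was not given. The deposited peak calls made up 4 lists, namely 1 per replicate, a pooled list called on both replicates together, and a replicated list of pooled peaks retained as reproducible. There was no second tissue, age or treatment, so the comparisons were between the replicates, between genomic locations, and between groups of genes within the tissue. Read depth was not given in the files, so the absence of a peak meant only that no region passed the authors' threshold at an unknown depth.

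The mark covered a small part of the genome, and the widest peak of the pooled and replicated lists spanned 13177 bp. Replicate 1 had 29017 peaks covering 32.5 Mb (1.19% of the genome) with a median width of 852 bp, and replicate 2 had 28305 peaks covering 33.1 Mb (1.22%) with a median width of 927 bp. The pooled list had 30374 peaks over 37.8 Mb (1.39%), and the replicated list had 22551 peaks over 35.4 Mb (1.3%) with a median width of 1406 bp. Enrichment in the replicated list was shifted upward, although its lowest value was 1.39 against 1.38 in the pooled list. Its median enrichment was 17.1 against 7.85 in the pooled list, and 93.0% of its peaks had a −log10 q of at least 5, against 70.5% of pooled peaks. All 22551 replicated peaks had the same coordinates and enrichment as a pooled peak, and 94.4% of those on chromosomes (21275 of 22539) overlapped peaks of both single replicates.

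How far separate pools of newborn intestine gave the same marked regions was asked by overlapping the replicate lists. At promoters, 92.8% of replicate 1 peaks and 92.4% of replicate 2 peaks were shared, against 63.0% and 64% of the peaks elsewhere. Over all peaks on chromosomes, 82.4% of those in replicate 1 (23908 of 29000, 95% exact binomial interval 82.0% to 82.9%) and 82.8% of those in replicate 2 (23408 of 28270, 82.4% to 83.2%) overlapped a peak of the other replicate by at least 1 bp. Peaks shifted at random along their chromosomes overlapped in 2.39% and 2.48% of cases. Sharing followed enrichment. In the weakest decile of peaks 42.2% and 42.1% were shared, in the fifth decile 97.7% and 98.7%, and from the seventh decile upward 100% in both replicates. Across 18147 peaks paired one to one, which are not independent replicates, Spearman's rho was 0.930 for enrichment and 0.961 for width, and the median distance between summits was 55 bp.

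**Figure D1:**
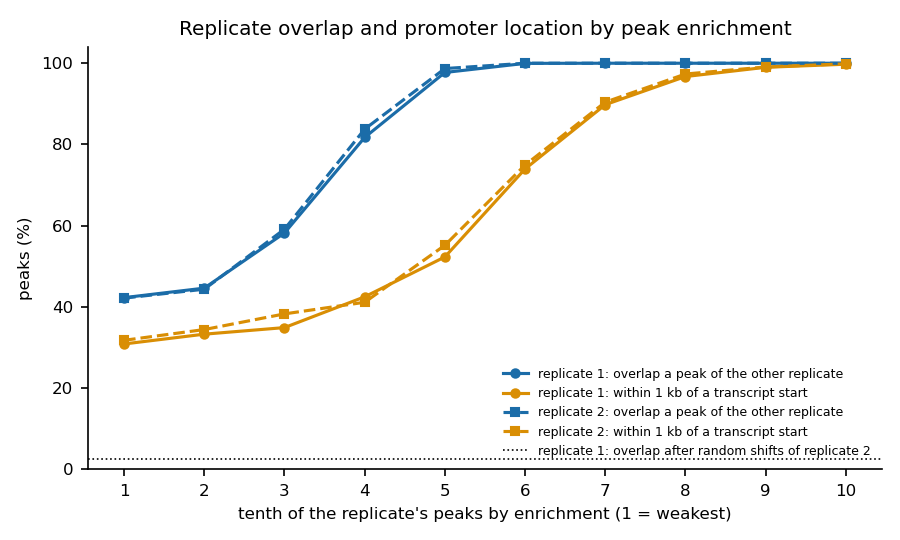
Percent of peaks (vertical axis) in each decile of peak enrichment (horizontal axis, weakest to strongest), per replicate, for peaks that overlapped the other replicate and for peaks within 1 kb of an annotated start. Sharing rose from 42.2% and 42.1% in the weakest decile to 100% from the seventh, and the promoter share from 30.8% and 31.7% to 99.8% and 99.9%.

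The strongest peaks without a counterpart in the other replicate were narrow and far down the ranking. In replicate 1 they lay near Ldlrad2 (chromosome 4, 137578201 to 137578726, mm10), in Fam49a, at Gm13657, near Gm8900 and in Tshz1. The Ldlrad2 peak was the best placed of these, at enrichment rank 14399 of 29000. In replicate 2 they lay at ccdc198 (chromosome 14, 49245100 to 49245459), in Vgll4, at Gm6787, at Crebzf and near Gm24886, with a best rank of 15209 of 28270 for ccdc198. Unshared peaks had a median width of 248 bp in replicate 1 and 262 bp in replicate 2, against 1144 bp and 1205 bp for shared ones.

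Where the marked regions lay was asked of the 22539 replicated peaks on chromosomes. Promoters held 16636 of them (73.8%), counting peaks within 1 kb of any annotated transcript start, against 10.2% on average and at most 11.4% for shifted peaks. Another 3607 peaks (16.0%) lay 1 to 10 kb from a start and 2296 (10.2%) lay farther than 10 kb. Promoter peaks were wider and stronger than the others. Their median width was 1716 bp against 659 bp and 642 bp in the other distance classes, their median enrichment was 25.8 against 4.90 and 5.23, and they held 87.2% of the bases under replicated peaks. In the single replicates the promoter share was 65.3% and 66.2%.

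Of 21938 protein-coding genes, 14689 (67%, 95% exact binomial interval 66.3% to 67.6%) had a replicated peak at a promoter. The share in the single replicates was 67.3% ± 0.0870 (SD, n = 2), and 14598 genes were marked in both. The interval covers counting error only. The genes that ranked highest by peak enrichment in both replicates were Msantd2 (ranks 7 and 9), Virma, a component of the N6-methyladenosine writer complex (18 and 11), Arid4b and Ggps1 at a shared promoter (20 and 11), Tnks, which encodes tankyrase (25 and 6), the small GTPase gene Rab12 (46 and 16), Dusp13 and Samd8 at a shared promoter (47 and 14), and Rnf114 and Spata2 at a shared promoter (50 and 2). Enrichment at Msantd2 was 52.7 in replicate 1 and 58.9 in replicate 2, against list medians of 7.85 and 9.06. Among other gene types, 34.9% of antisense RNA genes (1033 of 2959), 14.5% of lincRNA genes (850 of 5854), 14.4% of miRNA genes (318 of 2202), 7.99% of snoRNA and snRNA genes (231 of 2890) and 2.33% of pseudogenes (315 of 13523) were marked. Many of these marks were peaks at protein-coding starts. By peaks away from protein-coding starts alone, 5.07% of antisense RNA genes (150), 8.20% of lincRNA genes (480), 4.00% of miRNA genes (88), 2.56% of snoRNA and snRNA genes (74) and 1.46% of pseudogenes (197) were marked.

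CpG content, the known main correlate of this mark, separated marked from unmarked promoters. Of 11633 genes with a high-CpG promoter, 11414 (98.1%) were marked, against 2770 of 4690 (59.1%) in the intermediate class and 505 of 5615 (8.99%) in the low class. The classes differed in the same order in both replicates, with 98.2%, 59.5% and 9.58% in replicate 1 and 98.2%, 60% and 9.56% in replicate 2. Median domain width was 2146 bp in the high, 1482 bp in the intermediate and 1317 bp in the low class. Of the 219 high-CpG genes without a peak, 89 (40.6%) had at least 50% of the 32-base words around their starts repeated elsewhere in the genome, against 3 of 500 (0.6%) marked high-CpG genes drawn at random.

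How often genes of cell types, pathways and families were marked was asked of 37 lists, each compared with all other protein-coding genes. The tissue was not split into cell types, so a marked gene did not show which cells carried the mark. Transcription factor genes of the intestinal epithelium and most of its absorptive genes were marked. All 24 epithelial regulators were marked, from Cdx2, the caudal homeobox factor of intestinal identity, to Gata6 and Foxa1. So were all 18 genes of crypt and intervillus progenitors, among them Rnf43, a negative regulator of Wnt receptors, and Myc. Of 30 enterocyte genes for the brush border and nutrient uptake, 27 were marked (90% against 66.9% of other genes), including Vil1 (villin), the triglyceride transfer gene Mttp and the peptidase gene Enpep. The 3 unmarked enterocyte genes were the disaccharidase genes Sis and Treh and the enteropeptidase gene Tmprss15. By Fisher's exact test (two-sided, adjusted over the 37 lists) adjusted p was 0.000307 for regulators, 0.0037 for progenitors and 0.0126 for enterocytes.

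Genes of the secretory lineages were marked in part. Of 15 goblet genes 8 were marked, including Gfi1 and Atoh1, the determinant of secretory fate, while the mucin gene Muc2 and the trefoil peptide gene Tff3 had no replicated peak. Of 9 Paneth genes only Dll4 and Nupr1 were marked (22.2% against 67%, Fisher's exact adjusted p = 0.0153), and Lyz1 and Mmp7 were not. Dll4 is also in the Notch list, and whether Paneth cells were present at this age was not measured. The defensin genes Defa17, Defa5 and Defa24 had 96.4%, 96.4% and 52.2% of the sequence words around their starts repeated elsewhere. Of 24 enteroendocrine genes 16 were marked, including Pax6 and Insm1, with Pax4 and the glucagon gene Gcg unmarked. Of 14 tuft cell genes 7 were marked, among them Chat and Ptgs1, with Trpm5 and Gfi1b unmarked. The goblet (adjusted p = 0.322), enteroendocrine (1) and tuft (0.302) lists did not differ from other genes by Fisher's exact test, although all 3 fell below with only peaks of above-median enrichment (exact adjusted p = 0.0235, 3.77e-06 and 0.00131).

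Genes of the gut mesenchyme were nearly all marked. All 26 genes of fibroblasts and subepithelial mesenchyme were marked, led by Foxf1, a forkhead factor of gut mesenchyme, and Meis2, and 17 of 18 smooth muscle genes were, led by the tropomyosin genes Tpm1 and Tpm2, with only Kcnmb1 unmarked. Adjusted p was 0.000236 and 0.0182 by Fisher's exact test. The smooth muscle call was not kept in replicate 2 alone, where 16 genes were marked, 21.6 points above other genes. In replicate 1 alone 17 were marked, 27.3 points above. All 6 genes of the interstitial cells of Cajal were marked, including Etv1 and Gja1. Enteric neurons had 16 of 20 genes marked, led by Tbx2 and Hand2, with Nos1 and Vip unmarked. Enteric glia had 6 of 11, led by the receptor genes Erbb3 and Ednrb, with Plp1 and S100b unmarked. Mesothelium had 5 of 9, led by Tcf21 and Krt19, with Msln and Upk3b unmarked. These last 4 lists did not differ from other genes (exact adjusted p = 0.257, 0.302, 0.568 and 0.549). The Cajal list had the highest count possible at its size, so it could not have been called above.

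Most endothelial genes were marked, without a call against other genes in the main test, and few blood cell genes were. Blood endothelium had 15 of 18 genes marked, led by Fli1 and the VEGF receptor gene Kdr, with Tie1, Emcn and Vwf unmarked, and lymphatic endothelium had 5 of 7, led by Nr2f2 and Prox1, with Lyve1 and Ccl21a unmarked. Neither was called different from other genes (exact adjusted p = 0.276 and 1). The 7 lymphatic genes were too few for the list to be called above even if all were marked. Blood endothelium was called above in the pooled list (exact adjusted p = 0.0299) and outside the high-CpG class (0.0458). Only 8 of 27 leukocyte genes were marked (29.6% against 67%, exact adjusted p = 0.000307). The widest of these were Id2 and Gata3, and the general leukocyte gene Ptprc and the myeloid factor gene Spi1 had no replicated peak. Erythroid cells had 4 of 11 genes marked, led by Tfrc and Epor, with Gata1 and Alas2 unmarked (exact adjusted p = 0.0696).

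Genes of other organs were marked less often than other protein-coding genes in most, but not all, of the lists. The stomach list had 2 of 13 genes marked (Sox2 and Atp4a, with Gkn1 and Gkn2 unmarked), testis and oocyte 2 of 18 (Gdf9 and Dazl, with Prm1 and Prm2 unmarked), liver 5 of 17 (led by Apoh and G6pc, with Alb and Afp unmarked), lung epithelium 3 of 10 (led by Nkx2-1 and Abca3, with Sftpa1 and Sftpb unmarked), exocrine pancreas 5 of 15 (led by Nr5a2 and Spink1, with Cpa1 and Cela1 unmarked), skeletal muscle 5 of 15 (led by Mylpf and Pax3, with Myod1 and Myf5 unmarked) and epidermis 4 of 12 (led by Lor and Krt10, with Krt5 and Krt14 unmarked). Fisher's exact adjusted p ran from 1.08e-05 for testis and oocyte, through 0.000552 for stomach, 0.00648 for liver, 0.0182 for both exocrine pancreas and skeletal muscle and 0.0288 for lung, to 0.0382 for epidermis. Cardiac muscle (7 of 14, led by Hand1 and Ryr2, with Myh6 and Myh7 unmarked) and kidney (9 of 14, led by Hoxb7 and Lhx1, with Umod and Slc12a1 unmarked) did not differ (exact adjusted p = 0.302 and 0.829). Outside the high-CpG promoter class, where 31.8% of other genes were marked, the calls of these organs were lost except that of testis and oocyte (0 of 13, exact adjusted p = 0.044). Marked there were 4 of 16 liver genes (exact adjusted p = 0.811), 3 of 13 of exocrine pancreas (0.81), 1 of 12 of stomach (0.261), 2 of 10 of skeletal muscle (0.685), 0 of 6 of lung (0.383) and 1 of 9 of epidermis (0.533). Each of these shares still lay below that of other genes. Lung had the lowest count possible, so its call could not have been kept at that size. Forebrain neuron genes were marked more often than other genes. In that list 18 of 19 were marked, led by Bcl11b and Dlx1, with only Neurod6 unmarked (exact adjusted p = 0.0139). This call was not kept within the CpG classes. All 17 of its genes in the high-CpG class were marked, against 98.1% of others, and 1 of 2 outside it. With only peaks of above-median enrichment the forebrain list lay below other genes, at −32.0 points (exact adjusted p = 0.00924).

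Shared cell machinery and signalling pathways were marked almost completely. All 21 proliferation genes were marked, led by Mki67 and Plk1, as were all 27 Wnt pathway genes, led by Wnt5a and Fzd5, and all 26 Hedgehog and BMP pathway genes, led by Ptch1 and Id2. The Notch list had 16 of 17 marked, led by Hes1 and Notch4, with Mfng unmarked. Among protein complexes, 80 of 83 cytosolic ribosomal protein genes (led by Rpl18 and Rps2, with Rpl10l and Rpl39l among the unmarked), 74 of 75 respiratory chain genes (led by Ndufb10 and Atp5g2, with Atp5o unmarked) and 37 of 39 proteasome genes (led by Psmb3 and Psmb1, with Psma8 and Psmb11 unmarked) were marked. Fisher's exact adjusted p ran from 5.08e-11 for the respiratory chain and 6.59e-10 for ribosomal proteins, through 0.000184 for Wnt, 0.000229 for the proteasome, 0.000236 for Hedgehog and BMP and 0.000746 for proliferation, to 0.0284 for Notch. The sensory receptor families were nearly unmarked. Of 1093 olfactory receptor genes 3 were marked (0.274% against 70.5%), namely Olfr56, Olfr94 and Olfr1033, and of 327 vomeronasal receptor genes only Vmn1r4 was (0.306% against 68.0%, exact adjusted p = 4.64e-156). At least 50% of the sequence words around the start were repeated elsewhere for 105 vomeronasal and 25 olfactory receptor genes.

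In total 14 lists lay above other genes and 11 below. These tests describe this pair of pools, and genes are not replicates. Within the high-CpG class testis and oocyte was the list that lay below (2 of 5 against 98.1%, exact adjusted p = 0.00237). No list of these sizes could lie above there, since nearly all other genes were marked: all 68 respiratory chain genes of the class gave p = 0.641 (exact). Outside it 9 lists lay above, an alternative chosen after the data were seen. There enterocyte genes were marked in 23 of 26 cases against 31.6% of others, smooth muscle genes in 13 of 14, blood endothelium genes in 7 of 10 and the mesenchymal list in 11 of 11, and 3 lists lay below, namely testis and oocyte, olfactory and vomeronasal receptors. The Paneth and leukocyte calls were lost there as well, with 1 of 8 and 2 of 21 genes marked against 31.8% of others (exact adjusted p = 0.665 and 0.0923). Also lost were those of the forebrain, proliferation, Wnt, Notch, ribosomal protein and Hox lists, which had between 1 and 5 genes in that class. With only replicated peaks of above-median enrichment, 9 lists lay above and 21 below, and the enterocyte, smooth muscle, enteric neuron, blood endothelium, forebrain and Hox lists were among those below, the enterocyte list at −29.7 points. The fibroblast list lost its call there, at −3.02 points (exact adjusted p = 0.869). Other alternatives ended the calls of enterocyte, forebrain, Notch and lung (gene 5′ ends only), smooth muscle and Notch (receptor families left out of the background), skeletal muscle and lung (a window of 2.5 kb), skeletal muscle (the pooled list) and lung (a −log10 q of at least 5, or above-median enrichment). The lung difference was −37.0 points in the main test. It was −36.4 with that q, −33.0 with above-median enrichment, −33.3 with gene 5′ ends and −17.8 with a window of 2.5 kb. Calls were gained below by erythroid genes (receptor families left out) and cardiac muscle (a −log10 q of at least 5), by goblet, enteroendocrine, tuft, cardiac muscle and kidney genes (above-median enrichment), and above by blood endothelium (the pooled list).

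**Figure D2:**
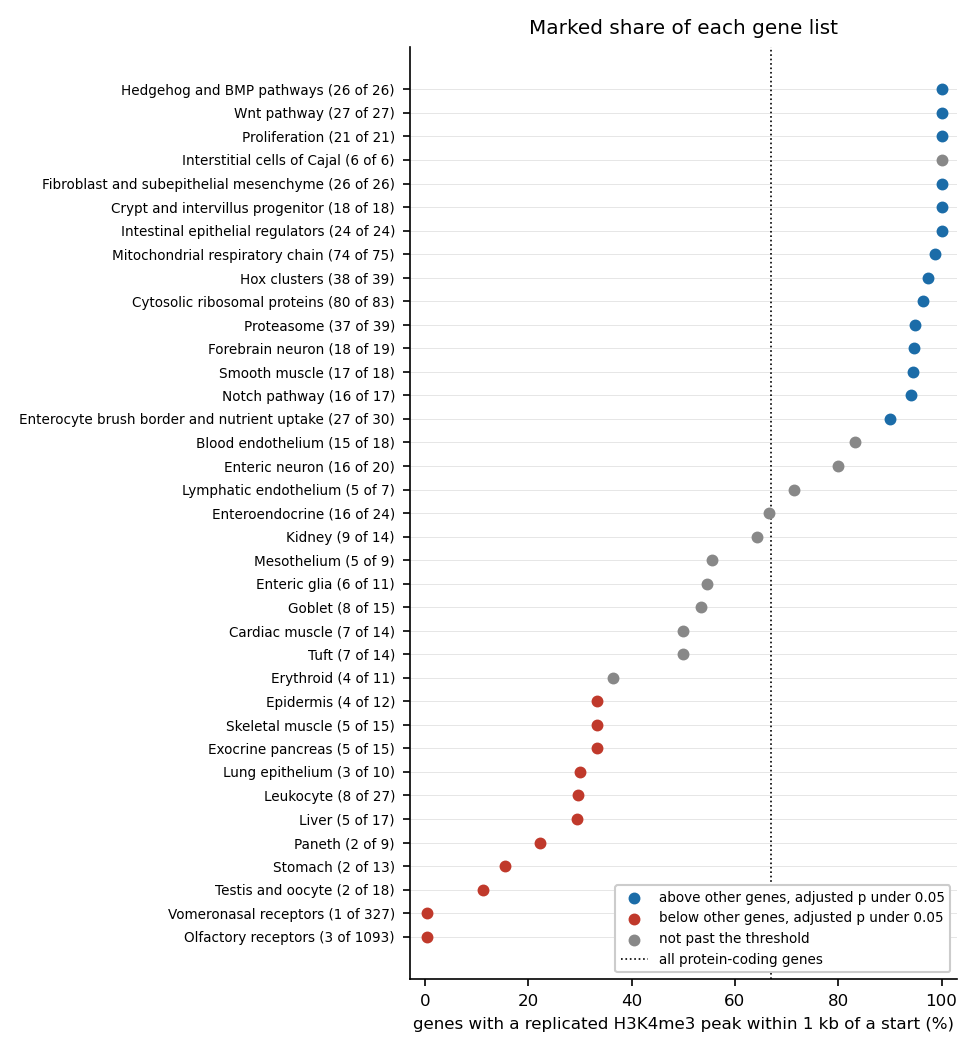
Percent of genes with a replicated peak within 1 kb of a start (horizontal axis) in each gene list (rows), with the number marked and the list's size. All 24 intestinal epithelial regulators were marked and 3 of 1093 olfactory receptor genes were, against 67% of all protein-coding genes.

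Which gene groups held wide domains was asked because wide H3K4me3 domains are known to mark genes of cell identity. Domains were replicated peaks joined over gaps of up to 1 kb. The widest lay at Foxf1, which had a domain of 18316 bp (chromosome 8, 121073011 to 121091326, mm10) and 15328 ± 2181 bp (SD, n = 2) in the replicates. It was followed by Meis2 (15955 bp, 15025 ± 2976), Tbx2 (15684 bp, 10258 ± 686), Zfp503 (14485 bp, 12426 ± 2679), a domain shared by Hoxa3, Hoxa5, Hoxa6 and the predicted gene Gm28308 (14342 bp, 14016 ± 215) and Onecut2 (14276 bp, 14438 ± 506). The next were Ptch1, which encodes the Hedgehog receptor (12869 bp, 11595 ± 1701), Pitx2 (12849 bp, 12738 ± 102.5), Foxa1 (12777 bp, 13309 ± 998) and Gata6 (12651 bp, 13000 ± 108). The median over all marked protein-coding genes was 2016 bp, with 1899 ± 26.9 bp (SD, n = 2) in the replicates. Across genes marked in both replicates, which are not independent, Spearman's rho of domain width was 0.909.

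Among the 29 lists with at least 5 marked members, epithelial regulators had the highest median domain width, 5143 bp against 2018 bp for random lists of marked genes (95% of them between 1640 and 2494 bp). Beside Foxa1 and Gata6, these included Klf5 (10621 bp, 10796 ± 943, SD, n = 2) and Cdx2 (10328 bp, 10027 ± 31.1). Fibroblast and subepithelial genes followed with 4235 bp, Hox genes with 3749 bp, Notch genes with 3722 bp (Hes1 8438 bp, 8237 ± 97.6), Hedgehog and BMP genes with 3405 bp (Id2 9029 bp, 6732 ± 2983) and smooth muscle genes with 3334 bp (Tpm1 10103 bp, 9816 ± 467). Wnt genes had 3179 bp (Wnt5a 7879 bp, 7839 ± 29.0), progenitor genes 2886 bp (Rnf43 6186 bp, 5874 ± 396) and ribosomal protein genes 2372 bp (Rpl18 7990 bp, 7842 ± 223). Narrower domains were found at enteroendocrine genes (1142 bp), at the 7 marked cardiac genes (1073 bp) and at the 5 marked exocrine pancreas genes (1066 bp).

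The two-sided permutation test gave 9 wider and 3 narrower lists among the 29 with at least 5 marked members. Adjusted p was 0.000967 for regulators, fibroblasts, Wnt, Notch, Hedgehog and BMP, and Hox, each of which had the smallest p that 10000 random lists can give, 0.0002 before adjustment (permutation). It was 0.0029 for smooth muscle, 0.0121 for progenitors, ribosomal proteins and cardiac muscle, 0.00166 for enteroendocrine and 0.0387 for exocrine pancreas (permutation). Among the 735 marked genes with the widest 5% of domains (4404 bp or more, 629 separate domains), 8 lists were over-represented by Fisher's exact test. Regulators had 15 of 24 genes there (62.5% against 4.91%, exact adjusted p = 6.68e-13), Hox 17 of 38 (1e-11, in 11 separate domains), fibroblasts 12 of 26 (1.1e-08), Wnt 9 of 27 (2.82e-05), Hedgehog and BMP 8 of 26 (0.000153), Notch 5 of 16 (0.00412), smooth muscle 4 of 17 (0.0364) and progenitors 4 of 18 (0.0393). The permutation test and Fisher's exact test both counted each gene separately. The 38 marked Hox genes are clustered neighbours in 32 separate domains, so both Hox p-values overstate the evidence.

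The other 17 lists did not pass the test of width. Enterocyte genes had a median of 2452 bp (permutation adjusted p = 0.106), goblet 2054 bp, tuft 1355 bp, enteric neuron 1868 bp, enteric glia 2329 bp, interstitial cells of Cajal 2182 bp, blood endothelium 2431 bp, lymphatic endothelium 2210 bp, leukocyte 2038 bp and mesothelium 2742 bp. Liver genes had 2048 bp, skeletal muscle 1217 bp, forebrain 2559 bp, kidney 2706 bp, proliferation 2394 bp, respiratory chain 2129 bp and proteasome 1861 bp. The Paneth, erythroid, stomach, lung, epidermis, testis and oocyte, olfactory and vomeronasal lists had too few marked members for the test. Against random lists matched on promoter CpG ratio, enterocyte genes were wider (2452 bp against 1471 bp, permutation adjusted p = 0.000644) and ribosomal proteins (0.311), exocrine pancreas (0.173) and cardiac muscle (0.0654) lost their calls. Without replicate 1 the enterocyte, tuft, blood endothelium and kidney lists passed the threshold (permutation adjusted p = 0.0148, 0.045, 0.00463 and 0.0243), and without replicate 2 the enterocyte and mesothelium lists did (0.0224 and 0.0435). In the pooled list goblet genes lay at −855 bp from random lists (permutation adjusted p = 0.00928), and enterocyte (0.0329), enteric glia (0.0497) and forebrain genes (0.0497) were wider. With a window of 2.5 kb skeletal muscle genes were narrower (permutation adjusted p = 0.00867). With gaps of up to 2.5 kb joined, blood endothelium (0.00725), mesothelium (0.0495) and forebrain genes (0.0497) were wider. Other ways of joining peaks ended the calls of smooth muscle (no joining), enteroendocrine (gaps of up to 2.5 kb) and progenitor genes (summed peaks within 5 kb). Regulators did not rank highest under every setting: with above-median enrichment fibroblast genes exceeded random lists by 4022 bp and regulators by 3115 bp. The cardiac and exocrine pancreas calls were also lost in the pooled list and with summed peaks, the cardiac call with a window of 2.5 kb or a −log10 q of at least 5, the exocrine call with no joining, and the ribosomal call with above-median enrichment. With 3 and 4 marked genes in replicates 1 and 2, the exocrine pancreas list could not be tested in either replicate alone.

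**Figure D3:**
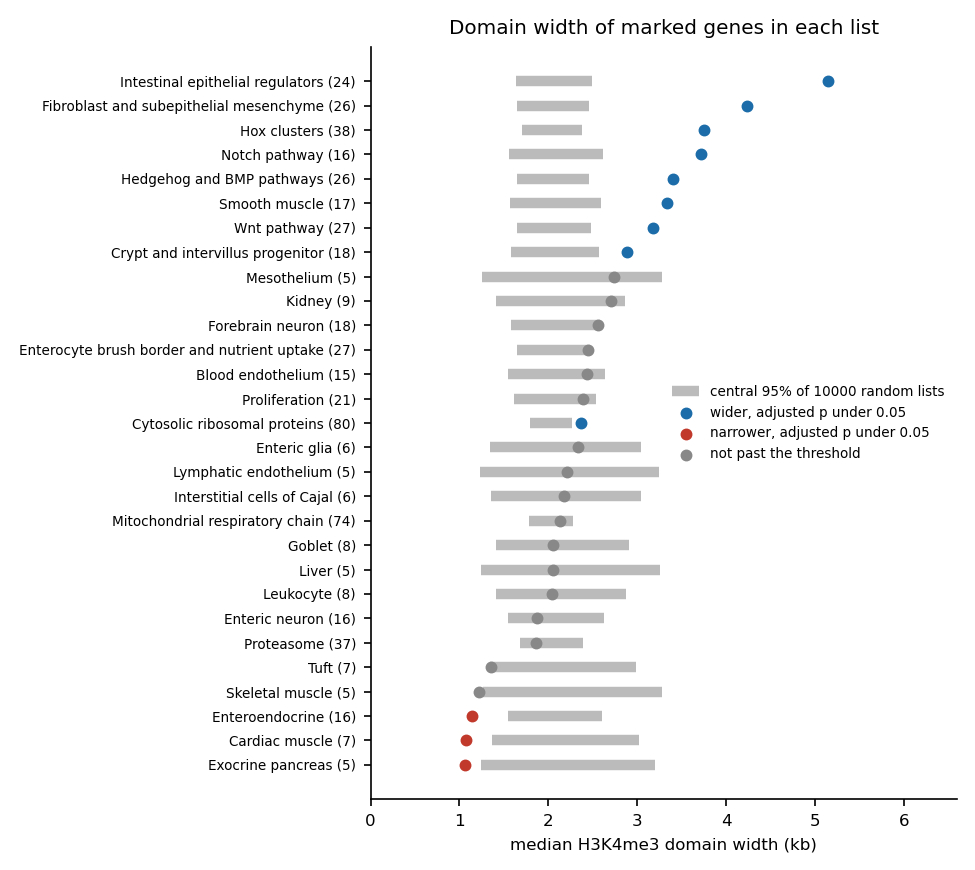
Median domain width in kb (horizontal axis) of the marked genes in each of 29 gene lists (rows, points), beside the range that holds 95% of random lists of the same size (grey bars). Intestinal epithelial regulators had 5143 bp, outside a random range of 1640 to 2494 bp.

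Hox genes, whose order along each cluster follows the body axis, were marked in 38 of 39 cases, including the genes at both ends of each of the 4 clusters. The HoxA cluster (chromosome 6, 52155590 to 52260880, mm10) had all 11 genes marked and 54.8% of its length under replicated peaks. HoxB (chromosome 11, 96194316 to 96368256) had all 10 genes marked and 31.4% covered, HoxC (chromosome 15, 102921103 to 103036852) all 9 genes and 20.8%, and HoxD (chromosome 2, 74668310 to 74765142) 8 of 9 genes and 32.3%. Hoxd12 was the unmarked gene, with a peak of 215 bp in replicate 1 and none in replicate 2. Hoxc11 had a domain of 411 bp in the replicated list and a peak in replicate 2 but not in replicate 1.

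In the replicated list domains were widest at the genes of the middle groups. The median was 3749 bp over paralogs 1 to 4, 5588 bp over paralogs 5 to 9 and 1887 bp over paralogs 10 to 13. Neighbouring genes can share a domain, so these medians count some domains more than once. The value for Hoxa3, counted with paralogs 1 to 4, was that of the domain it shared with Hoxa5 and Hoxa6. The replicates differed in the order of the anterior and middle groups, with 5288 and 3690 bp in replicate 1 and 3009 and 5756 bp in replicate 2. Paralogs 10 to 13 had the narrowest median in both, with 1890 and 1655 bp. Examples were Hoxb4 (11554 bp, 7599 ± 4997, SD, n = 2), Hoxb5 and Hoxb6 in a domain of 10707 bp, Hoxa1 and Hoxa2 in a domain of 11499 bp (11433 ± 75), and Hoxc12 (622 bp, 476 ± 105) and Hoxc10 (1060 bp, 686 ± 665) at the low end. Among posterior genes, Hoxa13 had 3949 bp (4326 ± 808), Hoxd13 1887 bp (1579 ± 440) and Hoxb13 1498 bp (1316 ± 132). As a list, Hox genes lay above other genes (exact adjusted p = 2.49e-05), but below them, at −19.7 points, with only peaks of above-median enrichment (exact adjusted p = 0.0233). No test between paralog groups was made.

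**Figure D4:**
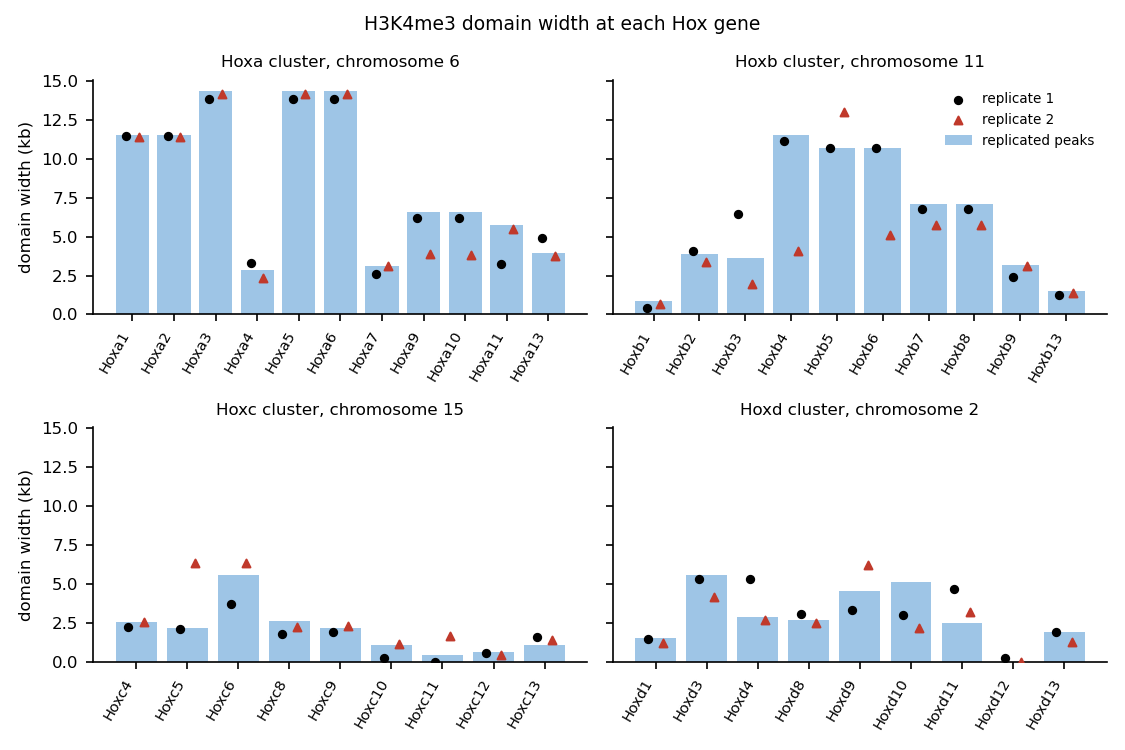
Domain width in kb (vertical axis) at each Hox gene in order along its cluster (horizontal axis), with 1 panel per cluster, showing both replicates and the replicated list. A domain of 14342 bp was shared by starts of Hoxa3, Hoxa5 and Hoxa6, and Hoxd12 had no replicated peak.

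Marked regions outside annotated promoters were described by the 2296 replicated peaks farther than 10 kb from any start, 884 of them inside genes and 1412 between genes. The strongest lay 32408 bp from Pum2 (chromosome 12, 8640352 to 8641726, mm10, between genes) at enrichment rank 1583. Next came a peak near Gm22614 (chromosome 3, 96499318 to 96503550, between genes), within 1 kb of several tRNA genes in the RefSeq annotation, and a peak near Gm47110 (chromosome 9, 67632000 to 67634743, between genes), within 1 kb of a RefSeq start of Tln2. A peak near Gm26773 (chromosome 14, 118088550 to 118090726, between genes) lay within 1 kb of a RefSeq tRNA gene, and a peak near Cluh (chromosome 11, 74637494 to 74639262) lay inside Ccdc92b. Of the 2296 peaks, 138 had an enrichment above the median of the replicated list. Counted beyond 50 kb there were 340, and the single replicates had 3367 and 3101 beyond 10 kb.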

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

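On scaffolds outside the assembled chromosomes, which none of the report's comparisons used, 12 replicated peaks were found. The count is above 3, the limit that a count of 0 allows, which shows only that peaks were called there. They lay on 4 scaffolds, were 265 to 2124 bp wide with a median enrichment of 6.64, and the best placed ranked 7944 by enrichment. No control samples were among the samples, and no explanation was tested.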

How the results depend on the processing

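Chosen after the data were seen were the list tests outside the high-CpG class, the stricter q and the left-out replicates for the marked share of each CpG class, and the left-out replicates for the median peak width. Leaving aside the tests split by CpG class, 17 of the 25 list calls at promoters kept direction and call under every alternative in which they could be tested, and 6 of the 12 width calls did. Read depth was not given, so what it limits could not be measured. Unless a limit of the setting is given, the cause was not tested for the changes below.

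The promoter share of peaks was 71.4% with a window of 0.5 kb, 79.7% with 2.5 kb, 63.5% with gene 5′ ends only, 76.9% with a −log10 q of at least 5, 96.8% with above-median enrichment, 62.2% in the pooled list and 65.3% to 66.2% in the lists of the single replicates. With above-median enrichment 9 lists lay above and 21 below, and the difference in marked share turned negative for enterocyte (−29.7 points), smooth muscle (−25.3), fibroblast (−3.02), enteric neuron (−33.0), blood endothelium (−41.9), forebrain (−32.0) and Hox (−19.7). With high-CpG promoters only, 0 lists lay above and 1 below, and the difference was +1.88 points for the Paneth, liver, stomach, olfactory and vomeronasal lists (1 member each in that class), exocrine pancreas (2), epidermis (3) and leukocyte (6). With 98.1% of other genes of that class marked, no list could lie above, and these lists had all their members there marked, so the sign says nothing about them. Outside that class 9 lists lay above and 3 below.

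The number of narrower lists was 0 with above-median enrichment, where 13 lists could be tested and none of the 3 narrower ones was among them. It was 1 with summed peaks within 5 kb and 1 against CpG-matched random lists. Over-represented lists in the widest 5% numbered 5 with summed peaks. The goblet median lay −855 bp from random lists in the pooled list. Overlap of replicate 1 and of replicate 2 was 69.0% and 70.8% when 50% of both peaks had to overlap, 77.6% and 77.7% with the summit inside the other peak, and 94.1% and 92.4% with a −log10 q of at least 5. Beyond 50 kb there were 340 peaks. With a −log10 q of at least 5, 97.9% of high, 57.6% of intermediate and 8.39% of low-CpG genes were marked. With either replicate left out these shares were 98.160% to 98.169%, 59.47% to 60.04% and 9.56% to 9.58%, and the median peak width was 852 to 927 bp.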

Other observations

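The genes and families in the opening paragraphs of this part, and the test against transcription factors of other tissues, were chosen only after values were seen. Low-CpG promoters were rarely marked, and the 505 marked ones were ranked by domain width without a test of any theme. Muc13, a transmembrane mucin gene, had a domain of 6169 bp (5246 ± 1587, SD, n = 2), Isx, an intestinal homeobox gene, 5960 bp (6000 ± 55.2), Pck1, a gluconeogenic enzyme gene, 5749 bp (4615 ± 1506), Hmgcs2, the ketogenic enzyme gene, 5350 bp (4313 ± 1237), and Fcgrt, which encodes the neonatal Fc receptor, 5475 bp (4713 ± 1524). Also among the 10 widest were Cpeb4 (5706 bp), Rnf151 (5706 bp, a domain that also touches Rps2, with no domain in replicate 1 and 5692 bp in replicate 2), Eps8l3 (4916 bp), Eno3 (4863 bp, a domain that also touches Pfn1 and ends before the 5′ end of Eno3) and Ugt2b34 (4752 bp). In all, 18 low-CpG genes lay in the widest 5% of domains. Of long noncoding RNA genes, Malat1 had a domain of 8589 bp (8208 ± 328) and the smooth muscle transcript gene Carmn 7402 bp (7027 ± 525).

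Among protocadherins on chromosome 18, the alpha cluster had 1 of 13 genes marked (Pcdhac2) and the beta cluster 1 of 22 (Pcdhb1), while the gamma cluster had 16 of 21. In replicates 1 and 2 the counts were 2 and 1 for alpha, 3 and 3 for beta, and 16 and 17 for gamma. All 13 alpha genes had high-CpG promoters. Of 402 tRNA genes 244 (60.7%) lay within 1 kb of a replicated peak, and 191 of them were reached by a peak away from protein-coding starts. When the tRNA genes rather than the peaks were shifted at random along their chromosomes, the share was 2.82% on average and at most 8.21%. The 4 marked protein-coding genes of the Y chromosome were Ddx3y, Eif2s3y, Kdm5d and Uty, and Xist was marked in the same pools (3137 bp, 3165 ± 264), which were of mixed sex per the labels. The peak with the highest −log10 q in every list lay at Hjurp and Trpm8 (chromosome 1, 88276043 to 88278167, mm10), at 683 in the replicated list, although its enrichment ranked 6275. No explanation was tested for these.

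Wide domains at epithelial regulators were set against promoter CpG content and against a trait of developmental genes, or of developmental transcription factors, of any tissue. The list's median of 5143 bp lay at percentile 100 of random lists matched on CpG ratio, which argues against the CpG ratio as the whole account. The matching used the highest ratio in any 500 bp window, so the length of CpG-rich sequence was not matched and its part could not be judged. It exceeded the median of 48 marked genes of 7 distant tissue lists by 2861.5 bp, but these include genes of differentiated cells such as Lor and Ryr2, so for developmental genes in general the explanations cannot be told apart. Against the 28 marked transcription factors of those lists (2594 bp) the difference was 2549 bp (permutation p = 3e-05), which argues against a trait shared alike by developmental transcription factors. Wide domains may go with factors active in this tissue, a hypothesis found and tested on the same data, with the Wnt, Notch, and Hedgehog and BMP lists wide as well and no other tissue measured.

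Forebrain neuron genes were nearly all marked, which might reflect their CpG content alone. Of random lists matched on promoter CpG ratio, 19.7% had fewer marked genes than the 18 of the list, and the matched median was 18 (95% of lists between 16 and 19). A complete list of 19 would have exceeded only 63.9% of them, so CpG content and a mark specific to these genes cannot be told apart by this count.

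Peaks far from annotated starts could be starts missing from the annotation, reads placed in repeats, or calls near the detection limit. Only 12.3% of the 2296 lay within 1 kb of a RefSeq start. For most of them this argues against starts that RefSeq holds and the main annotation lacks. Starts absent from both annotations could not be tested. Repeats took 11.3% of their bases against 33.7% when shifted (32.4% to 34.8%), which argues against an excess of repeat sequence in them. Promoter peaks had a similar share, 10.8%. Whether reads were misplaced could not be checked, since no reads were processed here. Of these peaks 94.0% lay below the median enrichment of the replicated list. The lists of the single replicates, which had not passed the step that gave the replicated list, held at most 1.47-fold as many far peaks. Weak calls and real distal marks therefore cannot be told apart without read depth.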
